A study of Mus musculus with 8 samples.

How the data were processed

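The data are RNA-seq read counts from the livers of 8 C57BL/6 mice, 4 fed a low-fat control diet and 4 a high-fat diet. Per the labels' protocols, livers were flash frozen, total RNA was isolated with a mirVana kit, and libraries were made with the Illumina TruSeq Stranded Total RNA kit. The authors deposited 1 table of whole-number counts per gene, with gene identifiers, names, types and coordinates, and its 8 count columns carry the sample titles of the labels. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Trimmomatic 0.32 and TopHat2 2.1.1 were used with mm10; the notes used here state no roles or settings. The counting tool, its strand setting and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical paralogs may therefore be split in ways that cannot be checked, and the larger overlaps of genes described in the text are given there.

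The table holds 28073 rows, of which 26673 had a count in at least 1 library. Total counts were 26643020, 27693825, 30013106 and 28682448 for control replicates 1 to 4, and 28312523, 27732127, 27710664 and 26846453 for high-fat replicates 1 to 4. Depth did not differ between the diets beyond the spread (exact two-sided permutation test of the means, p = 0.514, n = 4 per group; 70 splits, smallest possible p = 0.0286). The share of counts in the 10 most abundant genes was 17.8% ± 1.80 and 16.7% ± 0.304 (SD, n = 4; exact permutation p = 0.314). Of 5 such library measures, the small nucleolar RNA share and the TMM scaling factor reached the smallest possible p (0.0286 each, exact permutation). Genes detected had an exact permutation p = 0.0571. None passed after Benjamini-Hochberg adjustment (smallest 0.0714), but a lone measure at the smallest p could not have passed it. Replicate numbers follow the order of the samples, and the labels name no pairing. No 2 libraries of a group agreed within sampling noise: over genes with 50 or more counts in a pair, the mean chi-square per gene was 18.2 to 119.6 against about 1 for sampling alone. The labels call the samples biological replicates and name no batch.

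Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which kept 14088 genes holding 99.9% of the counts, library sizes were scaled by TMM, and the diets were compared with the quasi-likelihood test (glmQLFit, glmQLFTest) on all 8 libraries without covariates. P-values were adjusted by Benjamini-Hochberg over all genes and called at 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and means are given with the SD over 4 libraries. Fold changes are high-fat over control diet.

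Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 3 and a preset correlation of 0.01, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists. The design, the 38 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Of the lists, 36 had at least 3 tested members; mitochondrially encoded genes and pancreatic acinar markers had fewer and were not analysed here. Some genes stand in several lists. Named genes were the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 CPM in the higher group and no overlap between groups, the 4 smallest p-values in each direction, up to 4 called members per list by smallest p, every called nuclear receptor, and 16 genes given whatever their result. Gene models without an official symbol, pseudogenes and small RNAs were counted but not named, and not every gene that met the rule is described. A further 3 clock genes were added after their values were seen.

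The alternatives were RLE, upper-quartile and no normalization factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 4 libraries, removal of the 10 most abundant genes, 1 surrogate variable from sva 3.50.0, stricter thresholds, and leaving out each library in turn. Removal of per-library trends on exon length and GC content (loess, span 0.3) and leaving out 2 control libraries with adipose transcripts were added after seeing the data. Exon length and GC came from the GENCODE M21 annotation of the same genome, matched by gene identifier for 99.7% of tested genes. The edgeR step was tested on simulated data: counts for 14088 genes were drawn from the means and library sizes of this comparison, with 200 genes changed. It recovered 72% of 100 genes changed by a log2 fold of 1 and 98% of 100 changed by a log2 fold of 2, with 6 false calls, 3.41% of all calls. In a simulated list test 1 shifted list was recovered and 0 other lists were called. Its genes were drawn independently of each other, so it does not show the error rate for lists of correlated genes.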

Results

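RNA was sequenced from the livers of 8 C57BL/6 mice, an inbred laboratory strain, aged 21 to 22 weeks. The mice had been fed either a low-fat control diet or a high-fat diet, with 4 biological replicates per group. The series asks how a high-fat diet changes hepatic nuclear receptors, the ligand-activated transcription factors of the liver, and the genes they control. Total counts per library lay between 26643020 and 30013106, and 14088 genes had enough counts to be tested. At this depth 1 count stood for 0.034 to 0.039 CPM (counts scaled to a common library size), so genes with a mean under 1 CPM rest on few reads. In a principal component analysis of log2 CPM values the first component held 41.9% of the variance and separated the diets. High-fat libraries scored 18.8 to 39.2 on it and control libraries -30.8 to -11.9, with control replicate 3 closest to the high-fat group.

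On the high-fat diet the cholesterol synthesis pathway was lower nearly as a whole, while a part of the lipid droplet genes, a part of the targets of the receptors PPARA, CAR and PXR, and clock genes such as Dbp were higher. The time of collection is not given, so its share in these differences cannot be told. No gene list passed as a set by camera with an estimated correlation between its members. That setting was stricter even for the LXR target list, whose estimated correlation was -0.0093. Sqle, which encodes squalene epoxidase, fell from 113 ± 59.4 to 3.24 ± 1.15 CPM (mean ± SD, n = 4 per group), a log2 fold change of -5.12 ± 0.50 (SE) with an edgeR adjusted p = 0.00106. Cidea, which encodes a lipid droplet protein, rose from 0.542 ± 0.787 to 63.7 ± 40.5 CPM, a log2 fold change of 6.81 ± 0.83 (edgeR adjusted p = 0.00267). In total 529 genes were higher and 825 lower on the high-fat diet by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, so 60.9% of the called genes were lower. Of these, 167 of the higher and 164 of the lower genes changed by at least 2-fold. The groups' libraries did not overlap for 2431 of the tested genes, or 17.3%, against 2.86% by chance. The balance of directions depended on the scaling: with library totals alone, which moved the median log2 fold change of all genes to 0.10, 1111 genes were higher and 534 lower, 32.5% of calls. The normalization factors ran from 0.955 to 0.976 in the control libraries and from 1.02 to 1.07 in the high-fat libraries.

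**Figure D1:**
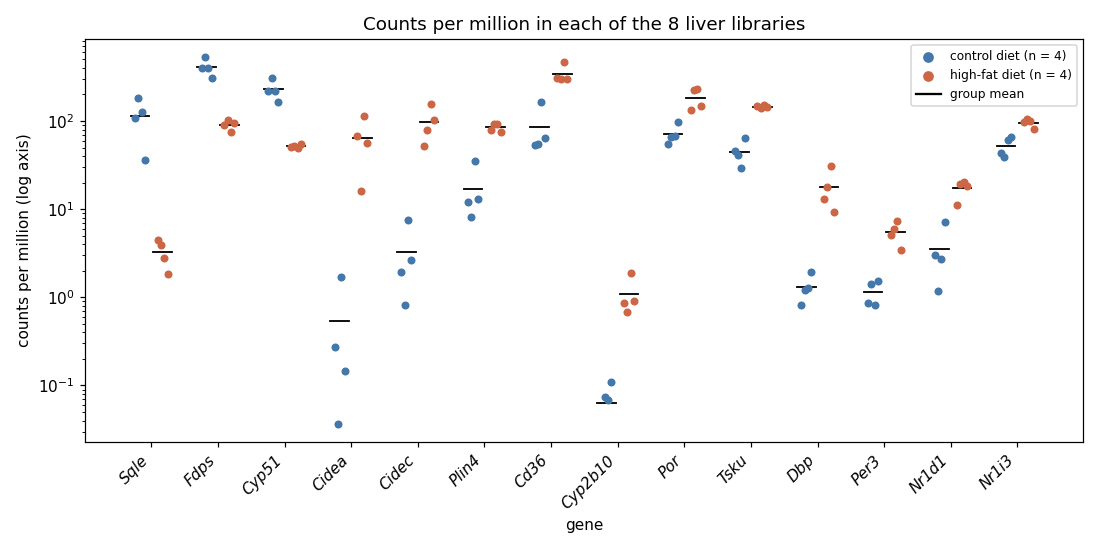
CPM of 14 named genes in each library (log axis, points; control diet blue, high-fat diet orange, n = 4 each, black lines are group means); a count of 0 for Cyp2b10 in 1 control library lies off the log axis and is not drawn. The control libraries average 113 CPM for Sqle and 0.542 CPM for Cidea, and the high-fat libraries 3.24 and 63.7 CPM.

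Of 27 measured genes of cholesterol synthesis and its regulation, 24 fell and none rose (25 lower when adjusted over the list alone), with a median log2 fold change of -1.42. Calls with small p-values in the list included Cyp51, lanosterol demethylase (-2.15 ± 0.16, edgeR adjusted p = 5.98e-04), and Fdps, farnesyl diphosphate synthase (-2.18 ± 0.16, edgeR adjusted p = 5.98e-04). The sterol reductase Tm7sf2 (-1.64 ± 0.14, edgeR adjusted p = 8.14e-04) and the sterol dehydrogenase Nsdhl (-2.03 ± 0.17, edgeR adjusted p = 8.14e-04) fell as well. As a set the list was lower than other genes by camera with a preset correlation (adjusted p = 4.18e-24), and adjusted p = 0.288 with an estimated correlation. Sqle lies at chromosome 15, 59315077 to 59331192, plus strand in mm10 (ENSMUSG00000022351.14), and Cyp51 at chromosome 5, 4081145 to 4104746, minus strand, where it overlaps Akap9 on the opposite strand, whose mean count was 70.5% of that of Cyp51. On the same strand Fdps overlaps the gene model Gm43738 and Tm7sf2 overlaps Vps51, with 62.8% and 24.0% of their counts.

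Of 28 genes of fatty acid and triglyceride synthesis 7 fell and none rose (9 lower when adjusted over the list alone), and camera called the list lower (adjusted p = 0.00216; adjusted p = 0.288 with an estimated correlation). The acetyl-CoA suppliers Acss2 (-2.10 ± 0.15, edgeR adjusted p = 5.98e-04) and Acly (-1.20 ± 0.17, edgeR adjusted p = 0.00461) fell, as did Acacb, an acetyl-CoA carboxylase (-0.88 ± 0.16, edgeR adjusted p = 0.0104). Srebf1, the lipogenic transcription factor gene, had 399 ± 106 and 587 ± 177 CPM on the control and high-fat diets (0.56 ± 0.27, edgeR adjusted p = 0.233), and the desaturase gene Scd1 23366 ± 6022 and 30759 ± 5270.0 CPM (0.40 ± 0.23, edgeR adjusted p = 0.316). Of 28 genes of apolipoproteins and lipoprotein metabolism 1 rose and 3 fell (1 and 4 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.105). Apom, a carrier of sphingosine 1-phosphate in HDL, fell from 188 ± 24.4 to 78.2 ± 12.1 CPM (-1.27 ± 0.13, edgeR adjusted p = 0.00131).

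A part of the lipid droplet genes and PPARG targets was higher, and Cidea and Cidec were among the largest rises of all. Of 22 members 11 rose and none fell (14 higher when adjusted over the list alone; median log2 fold change 0.68), with a camera adjusted p = 1.14e-08 and adjusted p = 0.360 with an estimated correlation. Cidec, a lipid droplet fusion protein, rose from 3.23 ± 2.95 to 96.8 ± 44.1 CPM (4.88 ± 0.58, edgeR adjusted p = 0.00248), and the fat storage gene Fitm1 rose by 0.98 ± 0.16 (edgeR adjusted p = 0.00673). The fatty acid transporter Cd36 rose from 84.5 ± 53.9 to 342 ± 82.0 CPM (2.02 ± 0.37, edgeR adjusted p = 0.0105), and Plin4, a droplet coat protein, by 2.31 ± 0.38 (edgeR adjusted p = 0.00784). Control replicate 3 had the highest control values of Cidea, Cidec, Cd36 and Plin4: without it the log2 fold change of Cidea was 8.69, of Cidec 5.74 and of Plin4 2.93. Plin4 overlaps Hdgfrp2 on the opposite strand, whose mean count was 49.5% of its own. Of 9 adipocyte markers 4 rose and none fell (5 higher when adjusted over the list alone), namely Cidec, Cidea, Plin4 and Cfd, the complement factor adipsin (4.74 ± 0.70, edgeR adjusted p = 0.00525; 5.50 without control replicate 3). The median of all 9 was 0.71. Camera called this list higher (adjusted p = 0.00227; adjusted p = 0.288 with an estimated correlation), and 3 of its 4 called members also stand in the lipid droplet list. The adipocyte transcript Adipoq, encoding adiponectin, had 42 and 32 counts in control replicates 1 and 4 and 10 or fewer in every other library. Without these 2 controls, a choice made after seeing the data, Cd36 and Plin4 no longer passed (edgeR adjusted p = 0.0665 and 0.0585, the highest of their alternatives; the lowest were 1.04e-04 and 2.51e-05). Their log2 fold changes were then 1.64 and 1.98, with fewer samples.

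A part of the targets of PPARA, the receptor that drives fatty acid oxidation, followed the same direction. Of 38 members 11 rose and none fell (22 higher when adjusted over the list alone), with a median log2 fold change of 0.50, a camera adjusted p = 9.96e-10 and adjusted p = 0.481 with an estimated correlation. Aldh3a2, a fatty aldehyde dehydrogenase, rose from 343 ± 116 to 1121 ± 164 CPM (1.71 ± 0.23, edgeR adjusted p = 0.00362), and the peroxisomal enzymes Hsd17b4 (0.55 ± 0.10, edgeR adjusted p = 0.00988) and Acaa1b (1.196 ± 0.21, edgeR adjusted p = 0.00993) rose as well. Cyp4a14, a fatty acid hydroxylase and PPARA target, was not called over all 8 libraries (2.12 ± 1.14, edgeR adjusted p = 0.285): control replicate 3 had 90.5 CPM and the other controls 6.36 CPM or less. Without that library Cyp4a14 passed with a log2 fold change of 5.28 and an edgeR adjusted p = 0.00292, the lowest of its alternatives, which ran up to 0.575. With library totals alone 18 PPARA targets were called higher. Of 16 LXR target genes 2 rose and none fell (2 higher when adjusted over the list alone), the sterol transporter pair Abcg5 (1.49 ± 0.21, edgeR adjusted p = 0.00483) and Abcg8 (1.22 ± 0.22, edgeR adjusted p = 0.0102), which lie head to head and overlap. Camera called the LXR list higher (adjusted p = 0.00227; adjusted p = 0.195 with an estimated correlation).

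Among 40 nuclear receptor genes, 4 rose and 5 fell (6 and 7 when adjusted over the list alone). The clock repressor Nr1d1, or REV-ERB alpha, rose from 3.54 ± 2.57 to 17.2 ± 4.07 CPM (2.28 ± 0.43, edgeR adjusted p = 0.0121), and the CAR gene Nr1i3 from 52.3 ± 13.0 to 95.5 ± 9.60 CPM (0.87 ± 0.16, edgeR adjusted p = 0.0122). The largest fall was that of Nr4a1, an immediate early receptor gene, from 7.09 ± 3.62 to 1.55 ± 0.777 CPM (-2.18 ± 0.41, edgeR adjusted p = 0.0125). Ppara rose by 0.47 ± 0.13 (edgeR adjusted p = 0.0472) and Nr1d2 by 1.02 ± 0.28 (edgeR adjusted p = 0.0475). Nr1d1 and Nr1d2 also stand in the clock list, and a difference in collection time between the groups is not excluded for them. Smaller falls were called for Nr2c1 (-0.57), Nr2f6 (-0.63) and Esrra (-0.34), with edgeR adjusted p = 0.0185, 0.0243 and 0.0312. Pparg did not pass (12.0 ± 5.05 and 24.4 ± 7.18 CPM, 1.02 ± 0.30, edgeR adjusted p = 0.0628), nor did the PXR gene Nr1i2 (0.33 ± 0.12, edgeR adjusted p = 0.139), the FXR gene Nr1h4 (0.18 ± 0.082, edgeR adjusted p = 0.215) or the LXR alpha gene Nr1h3 (-0.17 ± 0.10, edgeR adjusted p = 0.354). Nr0b2, the small heterodimer partner (0.36 ± 0.43, edgeR adjusted p = 0.657), and Hnf4a (0.019 ± 0.090, edgeR adjusted p = 0.921) did not pass either. Nr1d1, Nr1i3 and Nr4a1 passed with any 1 library left out, and the log2 fold change of Nr1d1 was 2.89 without control replicate 4. Among the fits with 1 library left out, Ppara passed only without control replicate 3 and Nr1d2 only without control replicate 4; otherwise edgeR gave adjusted p from 0.0541 to 0.118 and from 0.0629 to 0.121.

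Other receptor calls lay near the threshold. Nr2c1 did not pass without control replicate 2 or high-fat replicate 3 or 4 (edgeR adjusted p from 0.0542 to 0.0584; log2 fold change from -0.55 to -0.52), nor Nr2f6 without control replicate 2 or high-fat replicate 1, 2 or 3 (0.0625 to 0.0714; -0.63 to -0.57). Esrra was lost without control replicate 1 or 2 or any high-fat library (edgeR adjusted p from 0.0678 to 0.0801; log2 fold change from -0.35 to -0.30). These fold changes moved little. Pparg passed in 4 of its 19 alternatives, among them the fit without control replicate 3 (log2 fold change 1.24; adjusted p from 0.00633 to 0.165 over its alternatives). Nr1i2 passed with library totals alone (0.0498, in a range up to 0.299). That scaling called 8 receptor genes higher and 3 lower, and did not call Esrra. Camera did not call the receptor list (adjusted p = 0.673); its direction was down and its median -0.062, while its mean was 0.0069 and its median 0.033 with library totals alone. Nr1d1 overlaps Thra and Esrra overlaps Trmt112 on the opposite strand, with mean counts of 98.5% and 83.0% of their own. Of 19 coregulators 2 fell and none rose (2 lower when adjusted over the list alone). These were Ppargc1a, the coactivator PGC-1 alpha (-1.06 ± 0.18, edgeR adjusted p = 0.00936), and the deacetylase Sirt1 (-0.41 ± 0.079, edgeR adjusted p = 0.0135). With library totals alone 2 coregulators were also called higher. The coregulator list was not called by camera (adjusted p = 0.801, direction down, mean -0.052, median 0.034).

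A part of the targets of CAR and PXR, the receptors that induce drug metabolism, was higher. Of 35 members 13 rose and none fell (17 higher and 1 lower when adjusted over the list alone), with a camera adjusted p = 3.77e-07 and adjusted p = 0.396 with an estimated correlation. Cyp2b10, the classic CAR target, rose by 4.00 ± 0.57 (edgeR adjusted p = 0.00472) from a low base of 0 to 3 counts per control library against 19 to 56 per high-fat library. Por, the electron donor of microsomal P450 enzymes, rose from 71.2 ± 17.5 to 184 ± 50.9 CPM (1.37 ± 0.22, edgeR adjusted p = 0.00672), and Tsku, a secreted hepatic protein, from 45.01 ± 14.6 to 145 ± 5.86 CPM (1.69 ± 0.20, edgeR adjusted p = 0.00235). Cyp3a11, a PXR target, rose from 324 ± 192 to 1072 ± 424 CPM (1.73 ± 0.40, edgeR adjusted p = 0.0282). It did not pass without control replicate 1, 2 or 4 or high-fat replicate 3 or 4 (edgeR adjusted p from 0.0592 to 0.0778). Cyp2a4 rose by 5.69 ± 1.10 (edgeR adjusted p = 0.0134), from 2 to 6 counts per control library against 38 to 554 per high-fat library. Its log2 fold change was 4.17 without high-fat replicate 3, and its reads could be shared with its near-identical paralog Cyp2a5. Cyp2a4 did not pass with limma-voom (adjusted p = 0.0569) or without the 2 controls with adipose transcripts (edgeR adjusted p = 0.107), and its log2 fold change was at least 4.17 in every alternative.

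The P450 genes of families 1 to 4 moved both ways. Of 56 members 10 rose and 6 fell (12 and 12 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.231). Cyp3a59 rose by 1.74 ± 0.15 (edgeR adjusted p = 8.14e-04) and Cyp2c67 fell (-0.68 ± 0.12, edgeR adjusted p = 0.0102). Among 58 phase II conjugating enzymes 6 rose and 5 fell (11 and 6 when adjusted over the list alone; camera adjusted p = 0.309). The glutathione transferase Gstm4 rose (0.61 ± 0.10, edgeR adjusted p = 0.00673) while Gstm6 fell (-0.58 ± 0.12, edgeR adjusted p = 0.0150), and reads of this gene family can be shared. Drug and organic ion transporters split evenly: 9 rose and 9 fell of 43 (12 and 10 when adjusted over the list alone; camera adjusted p = 0.546). The anion transporter Slc22a27 rose (3.27 ± 0.50, edgeR adjusted p = 0.00571; 2.64 without high-fat replicate 3) and the prostaglandin transporter Slco2a1 fell (-1.15 ± 0.17, edgeR adjusted p = 0.00535). Of 10 AHR target genes 2 rose and 1 fell (3 and 3 when adjusted over the list alone; camera adjusted p = 0.334). Ahr itself rose (0.54 ± 0.10, edgeR adjusted p = 0.0104), and its target Cyp1a2 fell from 176 ± 45.7 to 86.4 ± 16.2 CPM (-1.03 ± 0.20, edgeR adjusted p = 0.0127). Without the 2 controls with adipose transcripts neither passed (log2 fold change 0.42 and -0.74, edgeR adjusted p = 0.0742 and 0.0625), with fewer samples.

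NRF2 target genes, which serve the oxidative stress response, gave 6 rises and 2 falls among 23 members (9 and 2 when adjusted over the list alone). The list is not separate from that of the CAR and PXR targets: Gsta1, Gsta2, Gstm1, Gstm3 and Abcc4 were put in both. The epoxide hydrolase Ephx1 rose from 195 ± 61.6 to 461 ± 106 CPM (1.24 ± 0.22, edgeR adjusted p = 0.0103), and camera called the list higher (adjusted p = 0.00229; adjusted p = 0.481 with an estimated correlation). For FXR targets and bile acid genes 2 of 28 rose and 8 fell (6 and 12 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.160). With library totals alone 4 of them were called higher and 6 lower. Abcb4, the phospholipid exporter of bile, rose from 261 ± 39.8 to 514 ± 51.8 CPM (0.97 ± 0.12, edgeR adjusted p = 0.00286), and Akr1d1, a reductase of bile acid synthesis, fell from 217 ± 19.5 to 135 ± 5.21 CPM (-0.69 ± 0.075, edgeR adjusted p = 0.00174). Abcb11, the bile salt export pump, fell by 0.46 and Slc10a1, the bile acid importer, by 0.66 on the log2 scale (edgeR adjusted p = 0.0193 and 0.0200). Neither passed without control replicate 1 or high-fat replicate 4, with edgeR adjusted p from 0.0537 to 0.0581 for Abcb11 and from 0.0507 to 0.0578 for Slc10a1. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 44.97 ± 41.9 and 128 ± 25.6 CPM (1.51 ± 0.55) and did not pass (edgeR adjusted p = 0.123); without control replicate 4 it did, with a log2 fold change of 2.35 and an edgeR adjusted p = 0.00947, the lowest of its alternatives, which ran up to 0.247.

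Circadian clock genes changed in opposite directions. Of 19 members 8 rose and 4 fell (8 and 5 when adjusted over the list alone), and camera did not call the list as one set (adjusted p = 0.106), while fry called it higher (adjusted p = 0.00143). The clock output factor Dbp rose from 1.31 ± 0.464 to 17.8 ± 9.42 CPM (3.75 ± 0.41, edgeR adjusted p = 0.00173), and Ciart (2.70 ± 0.32, edgeR adjusted p = 0.00248), Per3 (2.24 ± 0.29, edgeR adjusted p = 0.00327) and Tef (1.35 ± 0.19, edgeR adjusted p = 0.00429) rose with it. The activator Arntl, or BMAL1, fell from 39.6 ± 4.42 to 19.2 ± 5.35 CPM (-1.05 ± 0.19, edgeR adjusted p = 0.0102), and so did Cry1 (-1.08 ± 0.24, edgeR adjusted p = 0.0225) and Npas2 (-1.32 ± 0.36, edgeR adjusted p = 0.0472). Arntl, Cry1 and Npas2 were chosen for naming after their values were seen. Cry1 did not pass without control replicate 1 or 2 or high-fat replicate 2 (edgeR adjusted p from 0.0544 to 0.0624), and of the fits with 1 library left out Npas2 passed only in that without control replicate 4 (otherwise 0.0501 to 0.104). Dbp overlaps Sphk2 on the opposite strand, whose mean count was 362% of its own, and Per3 overlaps Camta1 on the same strand (50.4%). Ciart overlaps C920021L13Rik on the opposite strand (43.2%). With library totals alone 8 clock genes were called higher and 2 lower, and Npas2 did not pass (edgeR adjusted p = 0.0516). The labels give no time of collection.

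Among 28 genes of glucose metabolism and insulin signalling 1 rose and 6 fell (2 and 7 when adjusted over the list alone), with no call by camera (adjusted p = 0.160). Irs2, an insulin receptor substrate, fell from 31.5 ± 11.1 to 8.24 ± 2.92 CPM (-1.93 ± 0.30, edgeR adjusted p = 0.00636), and the growth factor binding protein gene Igfbp2 from 199.6 ± 32.0 to 108 ± 14.2 CPM (-0.88 ± 0.13, edgeR adjusted p = 0.00538).

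A part of the genes that male livers express more than female livers was lower on the high-fat diet. Of 26 members 9 fell and none rose (19 lower when adjusted over the list alone), with a median log2 fold change of -0.83, a camera adjusted p = 6.68e-09 and adjusted p = 0.436 with an estimated correlation. The complement regulator gene Susd4 fell from 26.8 ± 7.50 to 9.20 ± 2.25 CPM (-1.54 ± 0.24, edgeR adjusted p = 0.00574) and the major urinary protein gene Mup21 from 256 ± 111 to 87.5 ± 24.4 CPM (-1.55 ± 0.29, edgeR adjusted p = 0.0124), though Mup genes share reads. Of 19 female-biased genes 4 rose and 1 fell (5 and 3 when adjusted over the list alone; camera adjusted p = 0.0809). Camera called this list in 5 of 19 alternatives (lowest adjusted p = 1.53e-04, without the low-count filter; highest 0.549, with library totals alone). The rises were those of Slc22a27, of Cyp2b10 and Cyp2a4, which also stand among the CAR and PXR targets, and of the thioesterase gene Acot3, which stands among the PPARA targets (2.32 ± 0.58, edgeR adjusted p = 0.0363). Acot3 did not pass without control replicate 1, 2 or 4 or high-fat replicate 2, 3 or 4 (edgeR adjusted p from 0.0604 to 0.0967), and its log2 fold change was 3.05 without control replicate 3. The labels do not give the sex of the mice. All 8 libraries carried the Y-linked transcript Ddx3y (2988 to 4279 counts) and 0 to 4 counts of Xist, the transcript of the inactive X chromosome. This argues against a difference in sex between the groups as the cause.

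A part of the hepatocyte genes of the periportal zone was lower: 10 of 20 fell and none rose (10 lower when adjusted over the list alone), with a camera adjusted p = 1.18e-05 and adjusted p = 0.3202 with an estimated correlation. Cdh1, E-cadherin, fell from 43.1 ± 12.8 to 12.1 ± 4.37 CPM (-1.83 ± 0.29, edgeR adjusted p = 0.00632). The urea cycle enzyme gene Cps1 fell from 7731 ± 2169.7 to 3831 ± 735 CPM (-1.01 ± 0.22, edgeR adjusted p = 0.0209), a call lost without control replicate 1 or high-fat replicate 1, 3 or 4 (edgeR adjusted p from 0.0508 to 0.0530). Of 19 pericentral genes 3 rose and 1 fell (3 and 1 when adjusted over the list alone). The rises included Slc13a3, a dicarboxylate transporter (0.84 ± 0.11, edgeR adjusted p = 0.00400), and Aldh3a2, which also stands among the PPARA targets. The fall was that of Cyp1a2 (-1.03 ± 0.20, edgeR adjusted p = 0.0127). Camera called the pericentral list higher (adjusted p = 0.0134; adjusted p = 0.481 with an estimated correlation), but not without control replicate 3 (adjusted p = 0.114, in a range of 1.15e-04 to 0.481 over all alternatives). With library totals alone 6 periportal genes were called lower and 5 pericentral genes higher.

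Transcripts of ribosomal proteins and of respiration had slightly lower medians. Of 83 cytosolic ribosomal protein genes 64 fell and none rose (78 lower when adjusted over the list alone), with a median log2 fold change of -0.31, a camera adjusted p = 1.36e-36 and adjusted p = 0.195 with an estimated correlation. Rps18 fell from 137 ± 6.01 to 95.7 ± 3.54 CPM (-0.51 ± 0.058, edgeR adjusted p = 0.00212), and so did Rpl27 (-0.39 ± 0.048, edgeR adjusted p = 0.00301) and Rpl22l1, a paralog of Rpl22 (-1.03 ± 0.13, edgeR adjusted p = 0.00303). Of 77 nuclear genes of oxidative phosphorylation 29 fell and none rose (50 lower when adjusted over the list alone; median -0.21), with a camera adjusted p = 1.88e-17 and adjusted p = 0.288 with an estimated correlation. The ATP synthase subunit gene Atp5g1 fell from 98.3 ± 7.30 to 63.7 ± 2.05 CPM (-0.63 ± 0.065, edgeR adjusted p = 0.00135), and the cytochrome oxidase subunit gene Cox7a2 from 132 ± 2.40 to 99.4 ± 3.37 CPM (-0.41 ± 0.053, edgeR adjusted p = 0.00320). Reads of ribosomal protein genes can be shared with their pseudogenes. Both lists hold short genes, and over all genes the fold change rose with exon length (Spearman rho = 0.13 across genes, which are not independent replicates). With library totals alone 46 ribosomal protein genes and 18 respiration genes were called lower.

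Few genes were called by edgeR over all genes in the lists for the unfolded protein and integrated stress response, histones, proliferation and acute phase proteins. Of 22 genes of the unfolded protein and integrated stress response 1 fell and none rose (1 lower when adjusted over the list alone; camera adjusted p = 0.357). It was Atf4, the central factor of the integrated stress response (-0.65 ± 0.10, edgeR adjusted p = 0.00575). Replication-dependent histone genes gave 2 falls and no rise among 43 (2 lower when adjusted over the list alone; camera adjusted p = 0.0721), with Hist1h4c at -0.50 ± 0.059 (edgeR adjusted p = 0.00248). Camera called the histone list lower in 7 of 19 alternatives (lowest adjusted p = 7.24e-05, with 1 surrogate variable; highest 0.803, with an estimated correlation). Of 22 proliferation genes 1 rose, the cyclin Ccnd1 (0.67 ± 0.18, edgeR adjusted p = 0.0475), a call that among the fits with 1 library left out held only without control replicate 2 (otherwise 0.0546 to 0.121). Ccnd1 overlaps Oraov1 on the opposite strand, whose mean count was 29.7% of its own. No proliferation gene was called when adjusted over the list alone, and camera gave an adjusted p = 0.228. Acute phase proteins gave 1 rise and 2 falls among 27 (2 and 6 when adjusted over the list alone; camera adjusted p = 0.694). DESeq2 called 1 of them higher and 5 lower, and limma-voom 1 higher and 4 lower. Orm3, an acid glycoprotein, rose from 2.196 ± 0.597 to 20.01 ± 7.15 CPM (3.19 ± 0.30, edgeR adjusted p = 0.00100), and the fibrinogen genes Fgb and Fgg fell by 0.61 and 0.60 on the log2 scale (edgeR adjusted p = 0.0462 and 0.0333). Both fibrinogen calls were lost without control replicate 1, 2 or 3 or high-fat replicate 2, 3 or 4 (edgeR adjusted p from 0.0693 to 0.117 for Fgb and from 0.0556 to 0.0899 for Fgg).

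Markers of other liver cell types gave few calls. Among 15 markers of recruited and lipid-associated macrophages 2 rose and 1 fell (4 and 1 when adjusted over the list alone; camera adjusted p = 0.105). Camera called this list in 4 of 19 alternatives (lowest adjusted p = 0.00411, without the low-count filter; highest 0.680, with an estimated correlation). The fall was that of Fabp5, a fatty acid binding protein also expressed outside macrophages, from 124 ± 73.5 to 8.86 ± 1.18 CPM (-3.81 ± 0.50, edgeR adjusted p = 0.00339). The rises, in Mmp12 (2.77 ± 0.75, edgeR adjusted p = 0.0475) and Cx3cr1 (1.23 ± 0.32, edgeR adjusted p = 0.0410), rest on means of 3.48 and 1.69 CPM in the high-fat group, and Cx3cr1 overlaps the far more abundant Wdr48 on the opposite strand. With 1 library left out, Mmp12 passed only without high-fat replicate 2 (otherwise 0.0504 to 0.117, with a log2 fold change of 1.69 without high-fat replicate 3), and Cx3cr1 only without control replicate 1 or high-fat replicate 2 (otherwise 0.0768 to 0.103). In the stellate cell and fibrosis list 1 of 24 genes rose, the lysyl oxidase gene Loxl2 (0.71 ± 0.19, edgeR adjusted p = 0.0475), and none passed when adjusted over the list alone. With 1 library left out, Loxl2 passed only without high-fat replicate 2 (otherwise 0.0711 to 0.0959). Camera called the fibrosis list higher (adjusted p = 0.0282; adjusted p = 0.767 with an estimated correlation), but not without control replicate 3 (0.148) or high-fat replicate 3 (0.110) or with library totals alone (0.136), in a range of 0.00172 to 0.767 over all alternatives.

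No member was called, over all genes or adjusted over the list alone, among 17 Kupffer cell and macrophage markers, 18 endothelial, 11 cholangiocyte, 9 lymphocyte, 5 neutrophil and 7 erythroid and blood markers. Their camera adjusted p-values were 0.342, 0.591, 0.591, 0.519, 0.208 and 0.0721, in that order. At an unadjusted p under 0.05 edgeR had 0, 2, 1, 1, 1 and 4 of them in the same order. DESeq2 called 1 endothelial and 2 erythroid markers higher, limma-voom called 0, and with library totals alone 2 endothelial markers were called higher. The erythroid list had a median log2 fold change of 1.13, and camera called it higher in 6 of 19 alternatives (lowest adjusted p = 5.26e-04, without high-fat replicate 3; highest 0.536, with an estimated correlation), so a difference in blood content is not excluded. The cholangiocyte list's test pointed up while its median was -0.20 and its mean -0.28.

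**Figure D2:**
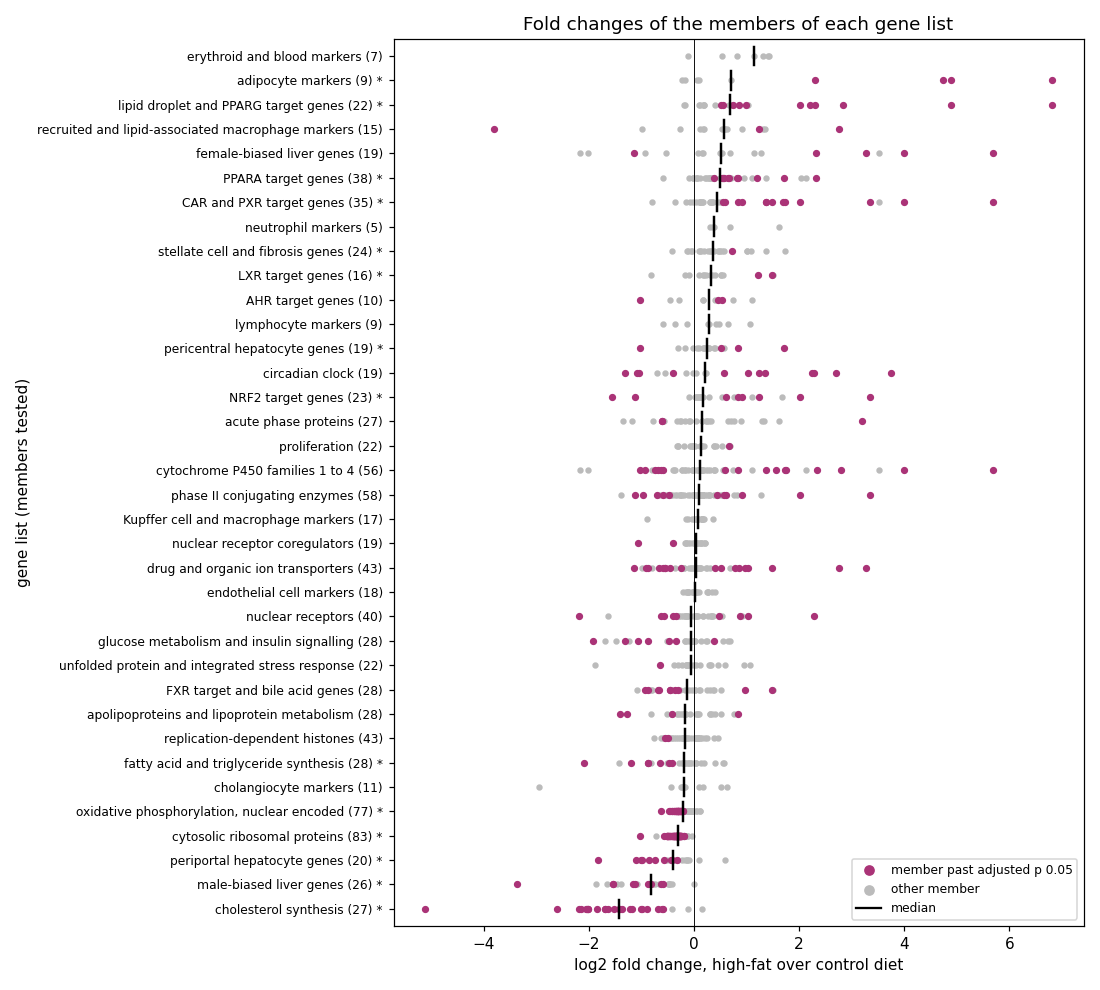
Log2 fold change, high-fat over control diet, of every tested member of the 36 gene lists (points; purple past an edgeR adjusted p of 0.05, grey not; black bars are list medians; numbers in brackets are members tested; a star marks a list called by camera with the preset correlation). Cholesterol synthesis has the lowest median at -1.42, and its members reach -5.12.

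Outside the lists, the largest rises included Themis, a T cell signalling gene (1.13 ± 0.844 to 22.5 ± 7.76 CPM, 4.29 ± 0.44, edgeR adjusted p = 0.00131), and Ly6d, a surface antigen gene (1.90 ± 1.35 to 35.4 ± 20.7 CPM, 4.20 ± 0.51, edgeR adjusted p = 0.00268); they stood at 4.91 and 4.83 without control replicate 3. Among genes named for size the largest fall was that of Adgrf1, an adhesion receptor gene, from 15.5 ± 5.61 to 0.330 ± 0.295 CPM (-5.55 ± 0.49, edgeR adjusted p = 8.14e-04; -6.35 without high-fat replicate 4). The acetylcholine receptor subunit gene Chrna4 (-4.03 ± 0.52, edgeR adjusted p = 0.00320), the phosphatase gene Acpp (-2.99 ± 0.49, edgeR adjusted p = 0.00745) and Fam222a (-2.86 ± 0.37, edgeR adjusted p = 0.00320) fell too. Small p-values were also reached by Sema5b, a semaphorin (1.62 ± 0.491 to 9.76 ± 0.287 CPM, 2.58 ± 0.19, edgeR adjusted p = 5.98e-04), Anxa2, a membrane-binding annexin (2.04 ± 0.17, edgeR adjusted p = 8.14e-04), and Gramd1b, a sterol transfer protein (1.81 ± 0.16, edgeR adjusted p = 9.11e-04). In mm10, Cidea lies at chromosome 18, 67343564 to 67367794, plus strand (ENSMUSG00000024526.8), Cyp2b10 at chromosome 7, 25897620 to 25926624, plus strand, and Adgrf1 at chromosome 17, 43270329 to 43324737, plus strand.

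Over all 36 lists camera called 14, 8 higher and 6 lower, with a preset correlation, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05, so no list call held with it. The estimated setting was stricter for reasons beyond the correlation of members. The LXR list had an estimated correlation of -0.0093, below the preset 0.01, yet its unadjusted camera p went from 6.94e-04 to 0.0109. A call lost with that setting therefore does not show that a list was unchanged. By fry, which asks whether a list's genes move one way on balance and does not compare it with other genes, 12 lists passed. These were 10 of the 14, in the same direction, and 2 that camera did not call, the circadian clock (higher) and the apolipoproteins (lower, adjusted p = 0.0414). The PPARA, NRF2, male-biased and fibrosis lists did not pass. Further lists not called over all 8 libraries passed in the same direction in some of the 19 alternatives: apolipoproteins in 5, cholangiocyte markers in 3, and P450 genes and phase II enzymes in 2 each. The FXR, glucose, clock, stress response, proliferation, Kupffer cell and neutrophil lists passed so in 1 each.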

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

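The tests of scaling, collection time, adipose tissue and a single deviating library, and the removal of length and GC trends, were chosen only after the patterns they concern were seen.

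In 15 of 248 groups of 4 libraries, 1 library stood far from the other 3 by Dixon's ratio, where chance, at about 1 in 20 groups, gives 12.4. Of these, 6 concern control replicate 3. That library had 165 CPM of Cd36 (others 53.7 to 64.7), 1.71 of Cidea (others at most 0.272), 90.5 of Cyp4a14 (others at most 6.36), 4.77 of Cyp3a59 (others at most 3.77), 10.9 of Nat8 (others at least 17.7) and 239.6 of Srebf1 (others at least 447). High-fat replicate 3 had 465 CPM of Cd36, 18.7 of Cyp2a4, 2.71 of Nr4a1 and 7.71 of Slc22a27, each above the other high-fat libraries. Control replicate 4 had 22.7 CPM of Anxa2, above the other controls, and 14430 of Scd1, below them. High-fat replicate 4 had 103 CPM of Atf4, above its group, and high-fat replicate 1 had 282 CPM of Cyp3a25, below its group, and 12.6 of Susd4, above it.

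Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 529 higher or 825 lower genes. No other split called more than 1 gene in a direction. The other splits mix the diets, so a difference between the diets adds to their spread and lowers their counts. The gene counts thus argue against a random grouping, but not against another factor that separates the same libraries. Chance cannot be excluded for the number of gene lists called by camera with the preset correlation. There 10 of the 35 splits, the real one included, called at least 14 lists, and another split called 17.

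Ribosomal protein and respiration genes were lower as sets by camera with the preset correlation but not with an estimated one (adjusted p = 0.195 and 0.288, and 0.185 and 0.282 after the correction below), and both hold short genes. With per-library length and GC trends removed, the median log2 fold change was -0.26 for ribosomal proteins (from -0.31) and -0.15 for oxidative phosphorylation (from -0.21), with 52 and 26 members called lower, of which 51 and 24 were also called before it, which argues against such a trend as the whole cause. A scaling factor moves all genes of a library alike, yet the ribosomal protein median differed from that of all genes by -0.31. The lowest of 10000 random lists matched on expression had a median of -0.15. Random lists hold unrelated genes, while this list had an estimated correlation of 0.23, so they do not show what chance gives for it. An effect of the diet on these transcripts stays open as a hypothesis, and RNA integrity was not tested.

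Clock genes shifted in opposite directions by phase. The median log2 fold change was 1.29 for genes of the Dbp phase and -0.80 for genes of the Arntl phase, a difference of 2.096. It stayed at 1.90 or above with any library left out, which argues against 1 deviating library. Livers of the 2 groups collected at different times of day would give the same difference, and since the labels give no time, this and an effect of the diet on the clock cannot be told apart. Such a difference in time could also move called genes outside the clock list, which was not tested.

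Of 9 adipocyte markers 4 rose in the high-fat livers, and adipose tissue left on the samples is a candidate explanation. Such tissue brings its abundant transcripts, yet the summed CPM of Adipoq, Plin1, Lep and Retn was not higher in the high-fat libraries (log2 ratio -1.97, exact permutation p = 0.429, n = 4 per group), with 3.38 and 2.92 CPM in control replicates 1 and 4 and at most 0.908 elsewhere. Over all 9 markers, a list fixed before the data were seen, camera with the preset correlation gave an adjusted p of at most 0.00959 with any library left out (0.288 over all 8 with an estimated correlation; median log2 fold change 0.71). The summed CPM argues against such tissue. The kept camera call adds little, since splits that mix the diets also gave many list calls at this setting. Cidec, Cidea, Plin4 and Cfd each kept their edgeR call with any 1 library left out. For these 4 genes this argues against 1 deviating library as the whole cause. Expression of these genes in hepatocytes on the high-fat diet is left as a hypothesis that the data here do not test.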

How the results depend on the processing

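The length and GC correction and the fit without the 2 controls with adipose transcripts were chosen after seeing the data. No called named gene turned its direction in any alternative, and 70 of 110 stayed past the threshold in all; 29 lost their call in at least 1 fit with a library left out. No gene called in the main comparison was called in the other direction under any alternative. The 529 higher and 825 lower genes became 1111 and 534 with library totals only, where the median of all genes moved by 0.10, and 316 and 497 with 1 surrogate variable; the cause was not tested. DESeq2 called 797 genes higher, and limma-voom, RLE, upper-quartile scaling, both filters and removal of the top 10 genes stayed within 1.5 times of both counts. Stricter thresholds left 167 higher and 164 lower at 2-fold, and 148 and 221 at an adjusted p of 0.01. Leaving out 1 library gave 293 to 636 higher and 432 to 843 lower genes, the lowest without high-fat replicate 3 and the highest without control replicate 3. Counts moved by over 1.5 times without control replicate 1 (350 and 539), control replicate 2 (313 and 473), high-fat replicate 3 (293 and 432) and high-fat replicate 4 (352 and 483), and for lower genes without high-fat replicate 2 (504). Without the 2 controls with adipose transcripts 282 were higher and 461 lower, with fewer samples. With trends on length and GC removed 534 were higher and 775 lower. The number of lists called by camera fell from 14 to 0 with an estimated correlation and was 14 to 21 elsewhere among the other camera fits. No paired analysis was run because the labels name no pairing and the replicate numbers follow sample order. The acute phase gene Saa1 fell with each replicate number in both diets. It went from 817 to 32.1 CPM in the control and from 789 to 80.0 CPM in the high-fat libraries. An order or batch shared by both groups was not tested.

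Reversed directions concerned lists and a gene that were not called, by camera adjusted p unless stated; their cause was not tested. With library totals only they were coregulators (0.980), acute phase proteins (0.654) and cholangiocyte markers (0.865). With 1 surrogate variable they were proliferation (0.301) and Kupffer cell markers (0.657). Without the 2 controls with adipose transcripts they were nuclear receptors (0.993), acute phase proteins (0.993), proliferation (0.251), Kupffer cell markers (0.0274, then past the threshold), endothelial markers (0.534) and neutrophil markers (0.951). With 1 library left out, lists that turned in some fits had adjusted p from 0.369 to 0.962 (acute phase), 0.00282 to 0.997 (Kupffer cells), 0.0138 to 0.899 (cholangiocytes), 0.362 to 0.733 (endothelium), 0.589 to 0.997 (coregulators) and 0.133 to 0.997 (lymphocytes). The log2 fold change of Hnf4a ran from -0.023 to 0.096 and was below 0 without control replicate 1 or 2 or high-fat replicate 1. The planned removal of mitochondrially encoded genes was not run. Depth limits the low genes: a control mean of 0.063 CPM for Cyp2b10 is 0 to 3 counts per library.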

Other observations

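Neither test below was chosen after its own result was seen, though both follow patterns noticed in these data.

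A part of the small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, was lower on the high-fat diet. Of 99 tested, 25 fell and 0 rose by edgeR's quasi-likelihood test at an adjusted p of 0.05, 56 were lower and 0 higher at an unadjusted p under 0.05, DESeq2 and limma-voom called 33 and 24 lower and 0 higher, 95 had a log2 fold change below 0, and the median was -0.64. Their share of all counts was 0.166% ± 0.0267 in the control and 0.127% ± 0.0121 in the high-fat libraries (SD, n = 4; exact permutation p = 0.0286, the smallest possible, and 0.0714 after adjustment over 5 library measures). Of 25 microRNA genes tested by edgeR 5 fell and 0 rose, with 8 lower and 0 higher at an unadjusted p under 0.05 and 5 lower by both DESeq2 and limma-voom. A library kit for long RNA captures such small RNAs only in part.

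Most snoRNAs are cut from introns of host genes, so lower host transcription may lower them. Across 90 snoRNAs with a tested host, the snoRNA and host log2 fold changes had a Spearman rho of 0.223 (permutation p = 0.0344 from 100000 resamples). These fall on 72 distinct hosts and are not independent replicates. Over the 90 snoRNAs the median log2 fold change of the host was -0.17, against -0.65 for their snoRNAs, and 21 of the distinct hosts fell and 1 rose. The rho lay between the bounds set for and against this explanation, so it stays undecided.

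Lower ribosomal protein transcripts might be part of a fall of the whole translation machinery. A list of 34 translation factors had a median log2 fold change of -0.071, with 2 members lower and 0 higher by edgeR (5 lower and 1 higher at an unadjusted p under 0.05; 5 and 2 lower and 0 higher by DESeq2 and limma-voom). Its camera p was 0.00833 with the preset correlation and 0.297 with an estimated correlation. The shift is smaller than the bound set for such a fall, so this remains undecided too.

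All 8 libraries carried the Y-linked transcript Ddx3y, with 2988 to 4279 counts, and 0 to 4 counts of Xist, the transcript of the inactive X chromosome.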
